A study of Mus musculus with 5 samples.

How the data were processed

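RNA bound to chromatin was sequenced from 5 libraries of mouse embryonic stem cells (ESC, pluripotent cells grown here on gelatin with serum and leukemia inhibitory factor). The cells carry a transgene for AGO2, the small RNA binding protein of the silencing complex, with HA and Flag tags, whose expression doxycycline switches on. Per the labels' protocols, cells of the doxycycline group received 2.5 µg/ml doxycycline for 15 h, the cytoplasm and nucleoplasm were discarded, and RNA of the chromatin pellet was made into strand-specific libraries after depletion of ribosomal RNA. The labels give 3 libraries with doxycycline and 2 without. They do not say whether these came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

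The deposited table holds 1 row per gene for the comparison of the groups. Per the submitters' processing notes the reads were demultiplexed with bcl2fastq 2.17.1 and handled with TopHat and Cuffdiff on build mm10; versions of the latter programs, the gene annotation, the strand setting and the library normalization are not given in the sources used here. The authors deposited 1 RPKM value (reads per kilobase, scaled to the mapped reads of a library) per group, per the file headers, with the libraries of a group already combined, so no value has an SD. The deposited log2 fold change is doxycycline over no doxycycline, and over the 15506 genes with both values above 0 it equals the log2 ratio of the RPKM values within 0.001 for 99.99% of genes. The authors' test score per gene was read but entered no calculation. The deposited p-value and q-value of each gene were used as given; recomputing the Benjamini-Hochberg adjustment from the deposited p-values moved no q-value by more than 2.9e-05. The smallest p-value is 5e-05, shared by 1056 genes at a q-value of 0.000528, so these genes cannot be ranked by p.

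The table lists 24345 genes, and 1 further row is emptied. The authors' program tested 11152 genes, left 13189 untested for lack of reads, failed on 3 (Cbx5, Kirrel and Smarca4) and skipped 1 for excess depth (Rn45s, the ribosomal RNA precursor). Untested genes enter no count or list. The log2 fold change of 606 genes listed at 0 with doxycycline had become a spreadsheet error and was read as minus infinity, and 1387 genes listed at 0 without doxycycline read infinity. For medians, the 74 tested genes with a group at 0 took the largest finite fold change, and no fold is printed for them. A spreadsheet had turned 27 gene names into dates; 16 of these were tested and 5 called, and they are counted but not named. Of the genes the naming rule selects, 2 are not reported here. Several symbols share a row in 103 cases. The total reads per library are not in the table, so the depth is unknown, as is the counting error of each value. Genes with near-identical copies (histones, ribosomal proteins, Actb) and the 1752 tested genes whose loci overlap another tested gene are uncertain, since how shared reads were assigned is not stated.

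A gene was called changed at a deposited q-value of 0.05 or less. The design, the alternatives, 29 gene lists and 11 miRNA seed families were fixed before the data were examined, with a plan for values per library in case the table held them. For each list with 3 or more measured members (tested, with an RPKM of at least 1 in a group), the median log2 fold change was placed among the medians of 10000 random lists of the same size matched on mean RPKM in 20 bins. This permutes gene labels within bins. The two-sided permutation p was adjusted by the Benjamini-Hochberg method over 24 lists; 0.0002 is the smallest p the draws can give. Genes are not replicates, so these p-values describe these libraries. The share of called members was compared with that of the other tested genes by a two-sided Fisher's exact test, adjusted over the same lists. This test was not matched on RPKM or gene length, which can affect how easily a gene is called. Chromosomes were treated like lists. The RPKM minimum of 1 removed no tested gene.

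For miRNA sites, 3′ UTRs and coding sequences came from GENCODE M21, whose genome is the same assembly as mm10, joined by gene symbol; 10027 tested genes (89.9%) had a 3′ UTR of at least 30 bases. Genes with a match to miRNA positions 2 to 8 (7mer-m8) in the longest annotated 3′ UTR were compared with random sets matched on mean RPKM (10 bins) and 3′ UTR length (10 bins), adjusted over 11 families. All 16032 heptamers found in the 3′ UTRs of at least 50 genes were also ranked by residual fold change after regression on RPKM, 3′ UTR length and GC content.

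Named genes follow a rule: the Argonaute genes; the 10 largest rises and 10 largest falls among called genes with their own symbol, short RNA genes left out; and, per list, up to 4 called members with the largest fold changes, or the 2 most abundant members where fewer than 2 were called. Other genes given with values were chosen after their values were seen, whether or not this is repeated beside them. The tests were tried on simulated fold changes laid over the real RPKM values and UTR lengths. Each simulated gene varied independently and without an effect of GC content. The rates below therefore do not cover lists of genes that change together, nor sites that differ in GC content. In lists of 28 of the 11152 genes with no planted change, 4.5% of 200 lists had p at or under 0.05, and a planted log2 shift of 0.3 was found in 72% and of 0.5 in 98%. In lists of 6 these were 7%, 21% and 55.5%, so small lists can miss such shifts. For the 1786 genes with a miR-290 and miR-302 7mer-m8 site among 10027 genes, 5.5% of 200 simulations without a shift and 80.5% with a shift of -0.05 were found; for the 369 genes with the 8mer, these were 6% and 34%.

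Alternatives were q thresholds of 0.01 and 0.1, a fold minimum, recomputed adjustment, median centring, upper-quartile scaling, an RPKM minimum of 5, pseudocounts of 1 and 0.1, the 8mer site, the shortest 3′ UTR and the coding sequence. Those added later were the removal of overlapping loci and matching on GC content. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are those of the deposited loci on mm10, counted from 1.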

Results

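Chromatin-associated RNA was compared between mouse ESC in which tagged AGO2 had been induced with doxycycline (3 libraries, 2.5 µg/ml for 15 h) and the same cells without doxycycline (2 libraries). The series concerns silencing by miRNAs in the nucleus and its need for Argonaute proteins. This comparison asks how RNA at the chromatin differs between cells with and without doxycycline induction of the transgene. The data hold no protein values, so the amount of AGO2 in either group is unknown. Values are the authors' RPKM, 1 per group, and depth per library is unknown, so no SD is given. Fold changes are doxycycline over no doxycycline, and "rose" and "fell" are used only of genes at a q-value of 0.05 or less in the authors' deposited table.

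Ago2 itself rose. Its locus on chromosome 15 (73101625 to 73184947) stood at 45.7 RPKM without and 64.7 RPKM with doxycycline, a log2 fold change of 0.50 with a q-value of 0.00177 in the authors' deposited table. The labels do not say whether the transgene is of mouse sequence, so how much of its RNA is counted there is open. Ago3 was at 32.8 and 37.1 RPKM, with a log2 fold change of 0.18 and a q-value of 0.377 in the authors' deposited table. Ago1 (listed at 0 and 0.012 RPKM) and Ago4 (0.052 and 0.163 RPKM) were near 0 and not tested. Of 11152 tested genes, 2833 (25.4%) were called in the authors' deposited table, 1334 higher and 1499 lower with doxycycline. Upper-quartile scaling would add 0.14 to every log2 fold change; the smallest called change is 0.35 in size, so no call changes direction.

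The list of the integrated stress response, the program through which ATF4 adapts cells to amino acid shortage and other stresses, lay above matched lists. Among 28 measured members, 12 rose, 0 fell and 16 did not pass; adjusted over the list alone, 13 passed as higher and 1 as lower. The lipoprotein receptor gene Vldlr rose from 0.307 to 2.65 RPKM and the secreted glycoprotein gene Stc2 from 1.77 to 9.50 RPKM, log2 fold changes of 3.11 and 2.43 in the authors' deposited table. Aldh1l2, a mitochondrial folate enzyme, rose from 1.04 to 4.54 RPKM, and Gdf15, a secreted stress cytokine, from 6.48 to 21.6 RPKM. The asparagine synthetase gene Asns and the ATF4 feedback gene Trib3, outside the naming rule and chosen after their values were seen, rose from 90.2 to 150.9 and from 8.31 to 17.2 RPKM. Atf4 itself was at 113 and 124 RPKM, with a q-value of 0.534 in the authors' deposited table. The list's median log2 fold change of 0.46 lay at the 99.99th percentile of random lists matched on RPKM (adjusted permutation p = 0.0024 over 24 lists); with an RPKM minimum of 5 it was 0.30 over 24 members (adjusted permutation p = 0.0048). The share of called members, 42.9% against 25.4% of other genes, did not pass (Fisher's exact test, adjusted p = 0.0935).

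Targets of p53 also lay above matched lists, with 7 of 24 measured members rising and 1 falling. The lincRNA-p21 gene Trp53cor1 rose from 0.914 to 2.73 RPKM, Trp53inp1 from 25.5 to 44.6 RPKM, and the cell cycle inhibitor gene Cdkn1a from 11.1 to 18.1 RPKM. Gdf15 is in this list too, and Ei24 was the member that fell, to a log2 fold change of -0.55 in the authors' deposited table. Their median log2 fold change was 0.18, at percentile 99.7 (adjusted permutation p = 0.0206), and 8 members passed adjusted over the list alone. The share of calls, 33.3%, did not pass (Fisher's exact test, adjusted p = 0.451). Sesn2, a member of both lists, was at 24.5 and 29.4 RPKM and did not pass.

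Genes that respond to FGF and ERK signalling lay below matched lists. Of 17 measured members of the FGF/ERK feedback list, 9 fell, 0 rose and 8 did not pass, and 10 passed as lower adjusted over the list alone. Phlda1 fell from 19.5 to 4.40 RPKM and the transcription factor gene Egr1 from 13.4 to 4.51 RPKM, log2 fold changes of -2.15 and -1.57 in the authors' deposited table. The ERK phosphatase genes Dusp5 and Dusp6 fell from 8.75 to 3.99 and from 23.0 to 10.7 RPKM. The list's median of -0.48 was below all 10000 matched random lists (adjusted permutation p = 0.0016), and 52.9% of members were called (Fisher's exact test, adjusted p = 0.0485). In the overlapping list of immediate early and heat shock genes, 8 of 18 fell and 0 rose, with 10 lower adjusted over the list alone. Egr1 is shared; Myc fell from 5.51 to 2.54 RPKM, Ier3 from 10.2 to 5.60 RPKM and the chaperone gene Hspb1 from 44.6 to 26.2 RPKM. That list's median of -0.42 lay at percentile 0.06 (adjusted permutation p = 0.0067), and its share of calls, 44.4%, did not pass (Fisher's exact test, adjusted p = 0.168).

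**Figure D1:**
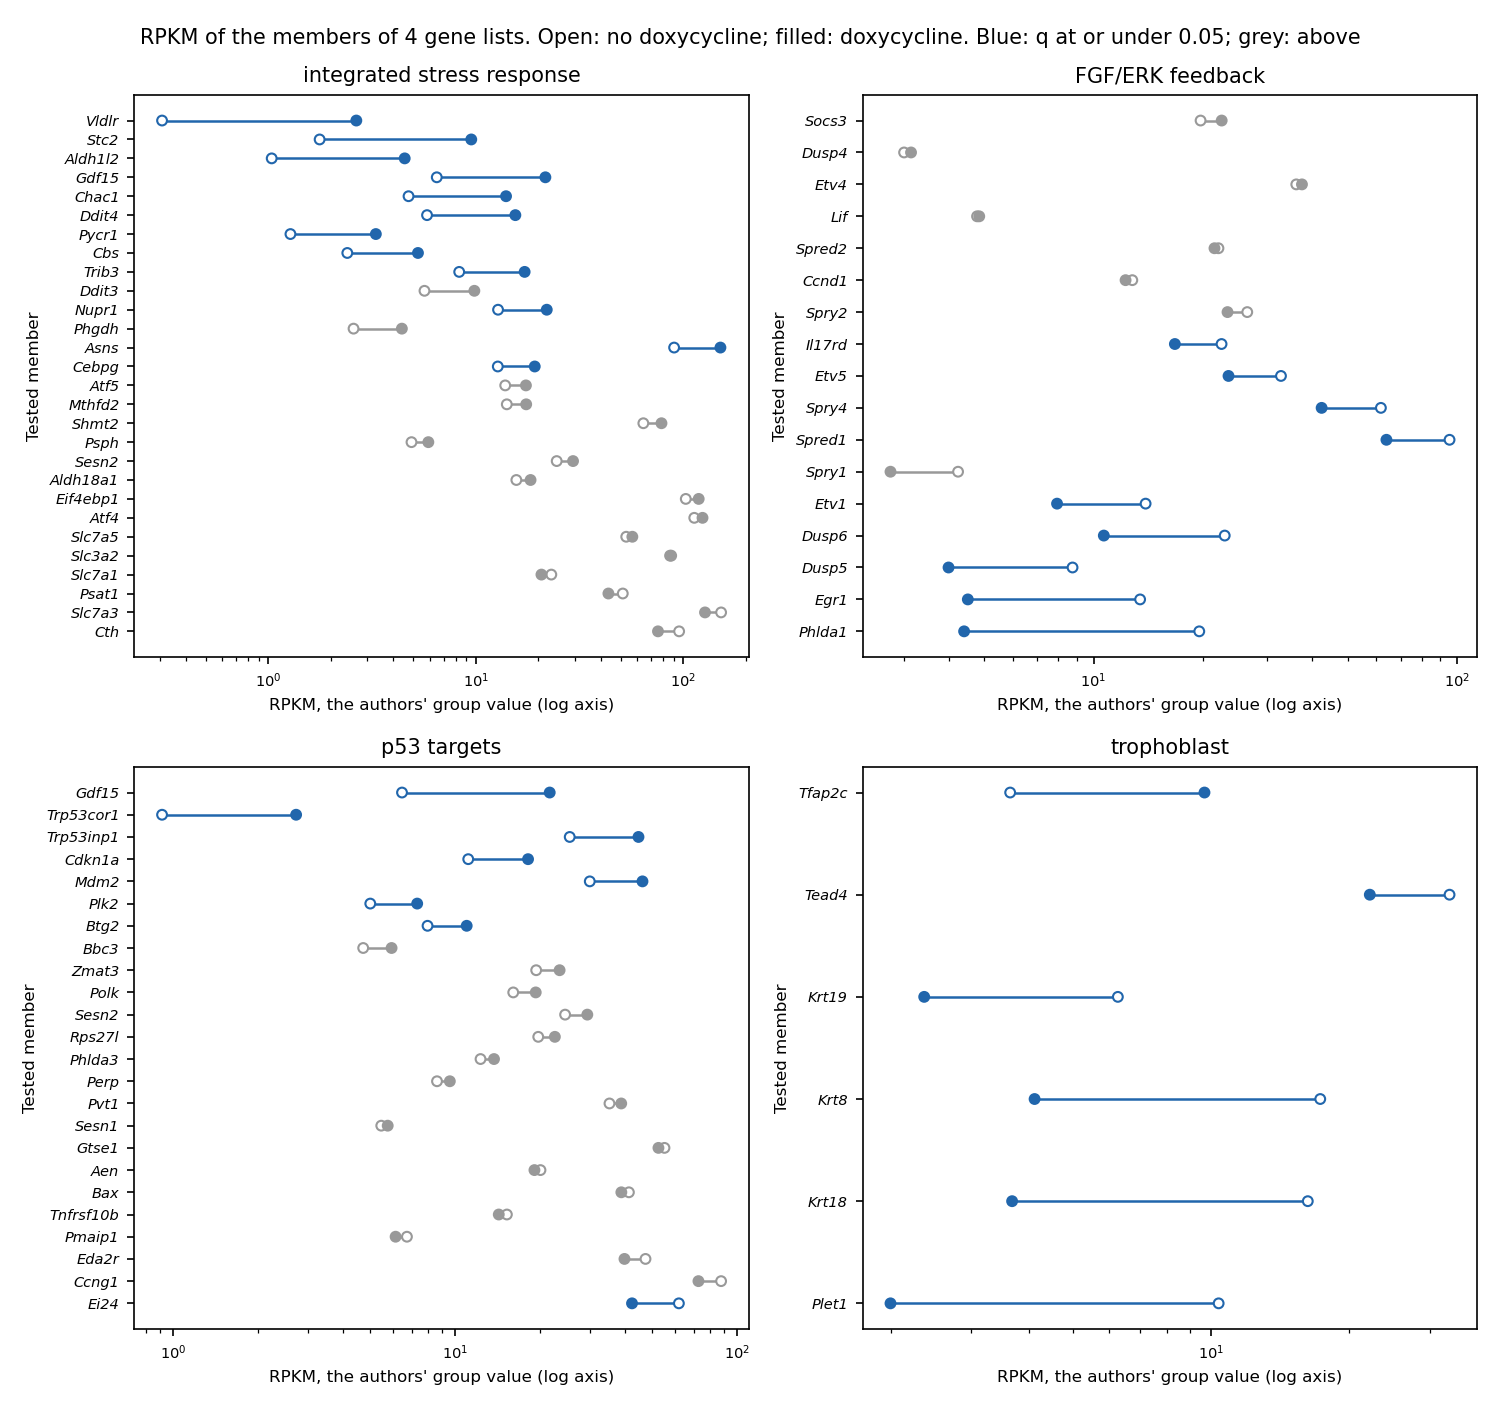
RPKM of tested members of 4 gene lists on a log axis, open circles without and filled circles with doxycycline, each the authors' group value with no error. Blue members passed a q-value of 0.05. In the stress list the 12 blue members lie to the right with doxycycline; in the FGF/ERK list the 9 blue members lie to the left.

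The pluripotency list lay below matched lists: of 34 measured members 15 fell, 1 rose and 18 did not pass, and 17 passed as lower and 2 as higher adjusted over the list alone. The osteopontin gene Spp1 fell from 215.8 to 78.7 RPKM, the BMP-responsive Id1 from 12.3 to 7.15 RPKM and Jam2 from 87.0 to 52.3 RPKM. Among core factors, chosen after their values were seen, Pou5f1 fell from 128 to 83.1 RPKM, Sox2 from 86.6 to 67.1 RPKM, and Nanog (108 and 126 RPKM, q-value 0.247 in the authors' deposited table) did not pass. Klf4 was the member that rose, from 14.6 to 22.1 RPKM. The median of -0.34 lay at percentile 0.46 (adjusted permutation p = 0.0282), and 47.1% of members were called (Fisher's exact test, adjusted p = 0.0232), but only 26.5% at a q threshold of 0.01 (adjusted p = 0.294). Without genes whose loci overlap another, the adjusted permutation p was 0.0789, the highest of a range from 0.0180 over its alternatives.

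Genes of the primed state and early neuroectoderm moved both ways, with 5 of 9 measured members falling and 3 rising. Otx2, a factor of the exit from naive pluripotency, fell from 23.6 to 6.77 RPKM, Sox11 from 3.15 to 0.978 RPKM and the DNA methyltransferase gene Dnmt3b from 31.8 to 19.7 RPKM, whereas the neural factor gene Sox1 rose from 1.22 to 2.89 RPKM. Adjusted over the list alone, 8 passed. The list's median of -0.55 lay at percentile 0.29 (adjusted permutation p = 0.0206), while the mean was -0.31; with an RPKM minimum of 5 in a group it lost 3 members and the adjusted permutation p was 0.531, the highest of a range from 0.0180 over its alternatives.

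Markers of other lineages were measured in few genes. All 6 measured trophoblast genes were called, 5 lower and 1 higher, as they were adjusted over the list alone. Plet1 fell from 10.4 to 2.00 RPKM, and the simple epithelial keratin genes Krt18 and Krt8 from 16.2 to 3.68 and from 17.3 to 4.12 RPKM, whereas Tfap2c rose from 3.64 to 9.67 RPKM. The median of -1.74 was below all matched random lists (adjusted permutation p = 0.0016). Of 6 endoderm genes, 3 fell and 2 rose: the basement membrane collagen genes Col4a2 and Col4a1 fell from 12.4 to 1.94 and from 12.9 to 3.42 RPKM, Sparc fell from 65.2 to 41.9 RPKM, and the laminin gene Lama1 rose from 15.8 to 25.2 RPKM, as did Lamb1, chosen after its value was seen, from 9.63 to 13.3 RPKM. That list stood at percentile 5.93 (adjusted permutation p = 0.285), and 5 passed adjusted over the list alone. Of 5 fibroblast genes, Thbs1 fell from 8.99 to 0.840 RPKM and the intermediate filament gene Vim from 61.4 to 29.5 RPKM, while the fibronectin gene Fn1 rose from 104 to 181 RPKM (percentile 15.3, adjusted permutation p = 0.501; 4 passed adjusted over the list alone).

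**Figure D2:**
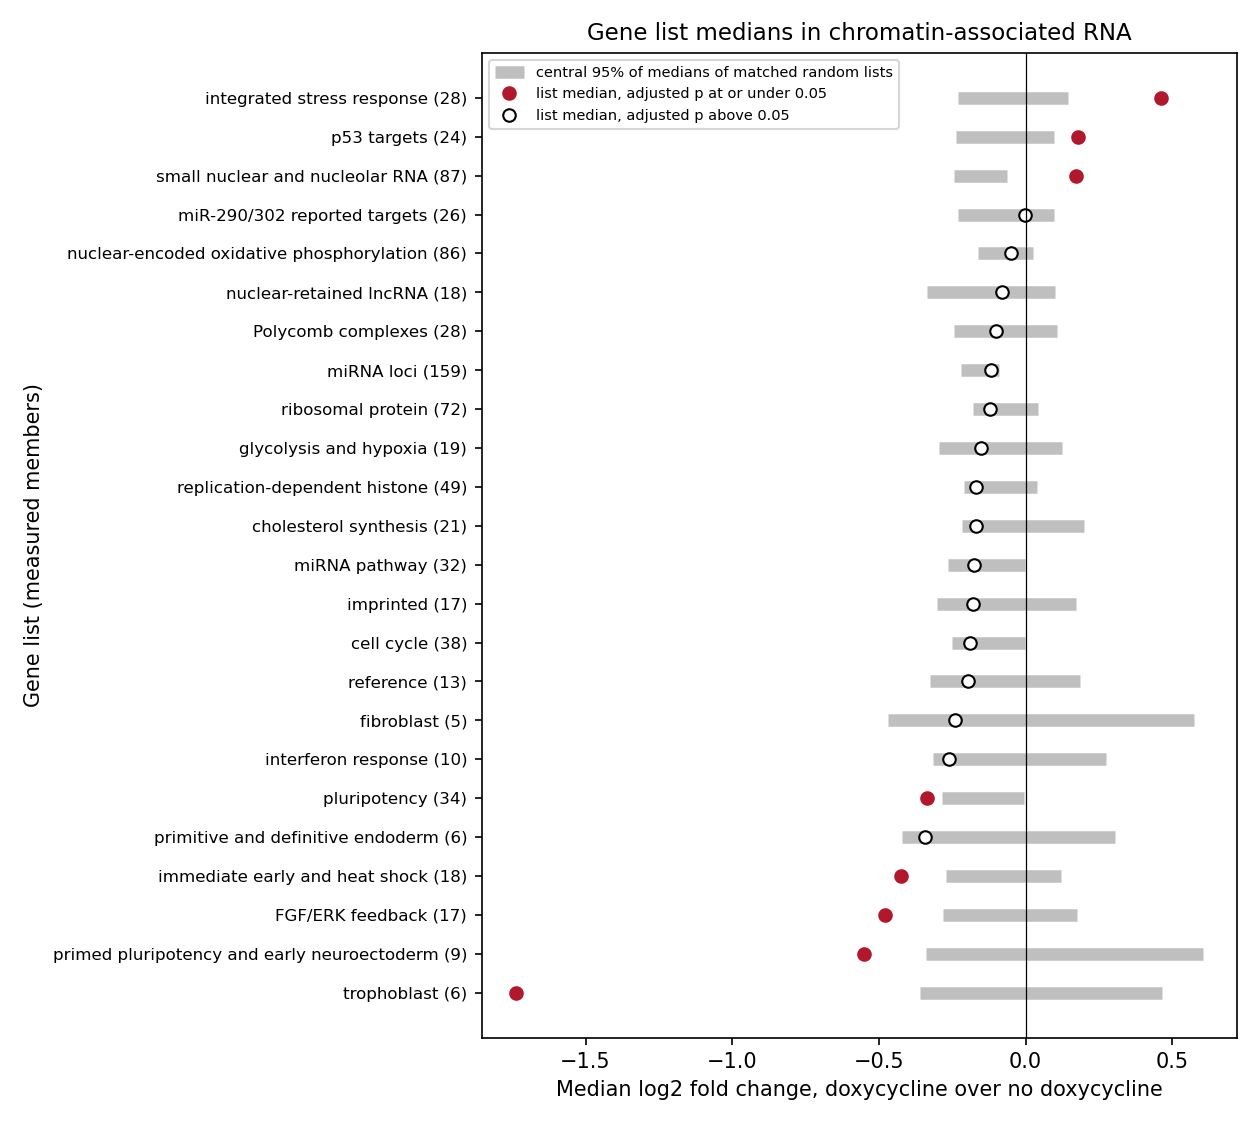
Median log2 fold change of the 24 gene lists with at least 3 measured members (number of members in brackets), with grey bars for the central 95% of medians of 10000 random lists matched on RPKM. Filled points, 3 above and 5 below their bars, have an adjusted p of 0.05 or less; trophoblast is lowest at -1.74 and the integrated stress response highest at 0.46.

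The largest single rises were of genes nearly silent without doxycycline. Kcnt2, a potassium channel gene on chromosome 1 (140246257 to 140656402), rose from 1.06 to 12.04 RPKM, a log2 fold change of 3.50 in the authors' deposited table. The complement protease gene C1s1 rose from 0.173 to 3.02 RPKM, Glp1r, the receptor of the gut hormone GLP-1, from 0.639 to 5.86 RPKM, and the phosphodiesterase gene Pde4c from 0.510 to 4.84 RPKM. Fndc4 (0.286 to 3.08 RPKM) and Steap1 (0.501 to 5.11 RPKM) rose as well. Sat2, Gm15850, 2310010J17Rik and Cox7a1 were listed at 0 without doxycycline and at 2.86, 2.76, 2.41 and 3.68 RPKM with it, and were called. Among the largest falls, Pglyrp1, a peptidoglycan recognition gene on chromosome 7 (18884690 to 18890438), went from 9.17 RPKM to being listed at 0. 1700057H21Rik fell from 19.4 to 1.56 RPKM and the sodium-proton exchanger gene Slc9a9 from 3.18 to 0.241 RPKM. The aldehyde oxidase gene Aox3 and the sodium pump gene Atp1a4 fell from 4.80 to 0.152 and from 4.83 to 0.189 RPKM, each with a q-value of 0.0453 in the authors' deposited table. The calcium buffer gene Casq1, the next locus to Atp1a4, fell from 4.72 to 0.340 RPKM, and Fam71f1, Lipg and Spink10 fell to between 0.201 and 0.522 RPKM.

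Genes of low abundance were more often higher and abundant genes more often lower. In the lowest decile of tested genes by mean RPKM (1.204 to 3.18 RPKM) the median log2 fold change was 0.45, with 296 genes higher and 121 lower. Every tested gene had at least 2.312 RPKM in its higher group. Genes with a mean below that value were thus tested only if the groups differed. The size of changes at the low end of this decile is therefore partly set by which genes were tested. In the highest decile (45.5 RPKM and above) it was -0.17, with 38 higher and 226 lower. Across genes, which are not independent replicates, Spearman's rho of mean RPKM and fold change was -0.30. Among called genes changed by at least 1 on the log2 scale, 521 of 875 (59.5%) were higher, against 47.1% of all called genes.

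**Figure D3:**
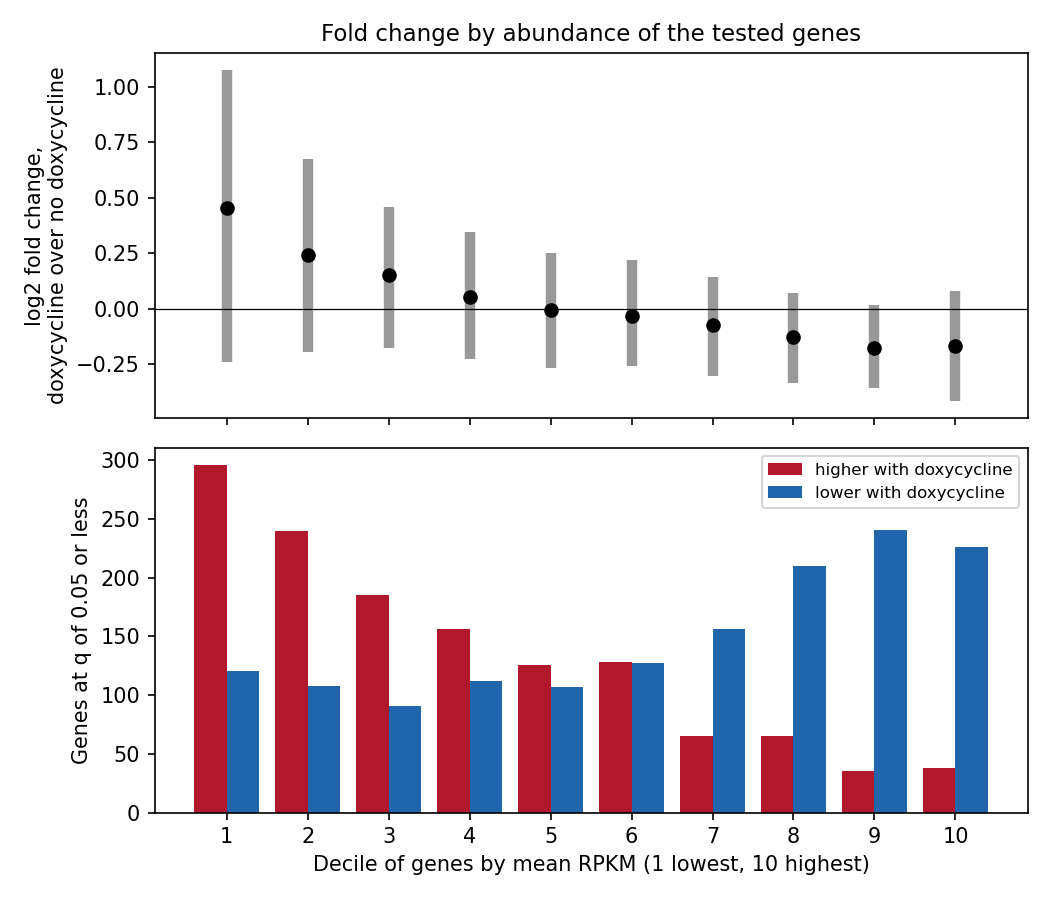
Upper panel, median log2 fold change (points) and interquartile range (bars) of tested genes in deciles by mean RPKM; lower panel, genes called higher (red) and lower (blue) in each. The median goes from 0.45 in the lowest decile to -0.17 in the highest.

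Genes of the miRNA machinery were called about as often as others. Of 32 measured members of the miRNA pathway list, 2 rose, 6 fell and 24 did not pass, a called share of 25% against 25.4% of other genes (Fisher's exact test, adjusted p = 1), and 6 passed adjusted over the list alone. Lin28a, the RNA binding protein that blocks let-7 maturation, rose from 3.40 to 12.1 RPKM and the uridylyl transferase gene Zcchc11 from 21.2 to 29.5 RPKM. The deadenylase gene Cnot6 fell from 72.9 to 43.7 RPKM and the decapping gene Dcp2 from 36.3 to 24.6 RPKM. The list's median stood at percentile 30.01 (adjusted permutation p = 0.650).

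Reported targets of the family of miR-290 and miR-302, the most abundant miRNAs of ESC, changed in both directions. Of 26 measured, 7 fell and 5 rose, and 8 passed as lower and 5 as higher adjusted over the list alone. Lefty2 fell from 11.7 to 5.29 RPKM, Ccnd2 from 3.41 to 1.94 RPKM and Lats2 from 28.6 to 16.7 RPKM, while Cdkn1a rose. The median stood at percentile 80.2 (adjusted permutation p = 0.501). Calls were more frequent than in other genes, at 46.2% (Fisher's exact test, adjusted p = 0.0485), but not at a q threshold of 0.01, at 26.9% (Fisher's exact test, adjusted p = 0.294), nor with an RPKM minimum of 5 (adjusted p = 0.0764).

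Across all tested genes with a 3′ UTR, the 1786 with a 7mer-m8 site of miR-290 and miR-302 had a median log2 fold change of -0.05 against -0.07 in sets matched on RPKM and UTR length. This is percentile 93.2 (adjusted permutation p = 0.252). The direction turned with the stricter 8mer site: those 369 genes had a median of -0.13, at percentile 0.21 (adjusted permutation p = 0.0484 over 11 families). Matched on 3′ UTR GC content too it did not pass (adjusted permutation p = 0.125), though the shift from matched sets hardly moved, from -0.063 to -0.059. Matching with GC content used 5 bins each of UTR length and GC content, against 10 of UTR length before. Over all alternatives the adjusted permutation p of these sites ranged from 0.0484 to 0.829. The site's heptamer ranked 10476th of 16032 counted from the lowest residual fold change. Among 7mer-m8 sites those of miR-21 had the lowest median, -0.12 over 804 genes (percentile 0.01, adjusted permutation p = 0.0044), and miR-15/16 sites lay above matched sets (percentile 99.7, adjusted permutation p = 0.0308); neither passed when 3′ UTR GC content was matched too (adjusted permutation p = 0.295 and 0.421, within ranges of 0.0110 to 0.815 and 0.0242 to 0.958 over their alternatives). The other ESC families, that of miR-17, miR-20, miR-93 and miR-106, that of miR-25/92 and miR-26, had adjusted p-values of 0.0711, 0.890 and 0.0990. For let-7 and the families of other tissues, miR-1, miR-122, miR-124 and miR-9, these were 0.830, 0.550, 0.186, 0.886 and 0.890.

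**Figure D4:**
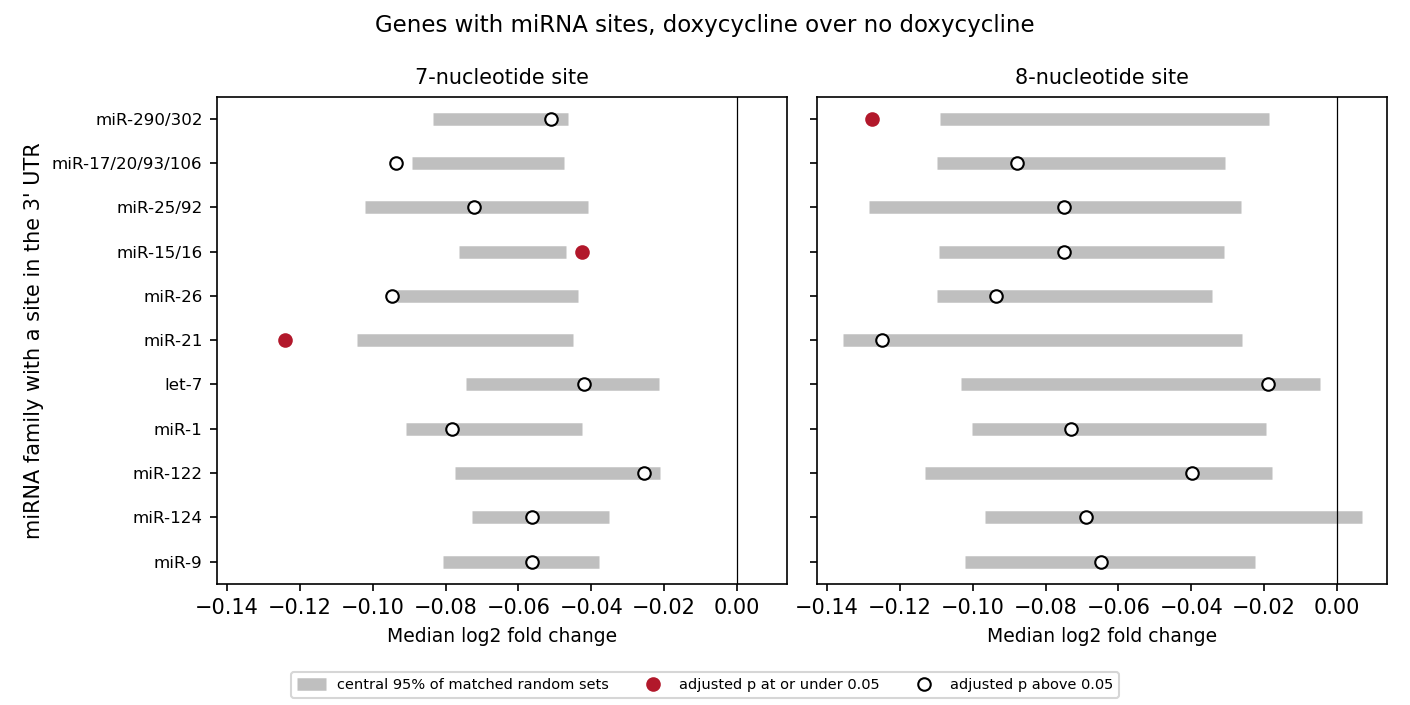
Median log2 fold change of genes with a 3′ UTR site of each miRNA family, for the 7-nucleotide site on the left and the 8-nucleotide site on the right, with grey bars for the central 95% of random sets matched on RPKM and 3′ UTR length. Filled points have an adjusted p of 0.05 or less. The point of miR-290 and miR-302 lies inside its bar at -0.05 on the left and below it at -0.13 on the right.

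Among nuclear-retained long noncoding RNAs 2 of 18 rose and 3 fell, and 5 passed adjusted over the list alone (percentile 69.0). Xist, which overlaps its antisense gene Tsix, fell from 28.3 to 8.65 RPKM and Neat1 from 627 to 393 RPKM, while Firre rose from 19.04 to 34.6 RPKM and Snhg11 from 19.5 to 52.1 RPKM. Imprinted genes split evenly, with 4 of 17 rising and 4 falling (percentile 18.98; 9 passed adjusted over the list alone). Peg10 fell from 103 to 32.6 RPKM and Plagl1 from 24.7 to 8.50 RPKM, and Grb10 and H19 rose from 2.76 to 6.03 and from 1.27 to 2.58 RPKM. Of 10 interferon response genes 4 fell, Oas1a (7.81 to 3.30 RPKM), Xaf1 (29.7 to 14.4 RPKM), Ddx58 (25.6 to 12.5 RPKM) and Ifitm3 (91.2 to 63.1 RPKM), and Stat2, chosen after its value was seen, rose (percentile 5.64; 7 passed adjusted over the list alone). In glycolysis and hypoxia 3 of 19 rose and 3 fell (percentile 30.04; 6 passed adjusted over the list alone): Vegfa rose from 7.45 to 28.6 RPKM and Slc2a3 from 141 to 217 RPKM, and Ndrg1 fell from 21.01 to 3.80 RPKM.

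Of 38 cell cycle genes 9 fell and 3 rose, the same counts as adjusted over the list alone (percentile 16.8). Cdc20 fell from 61.3 to 30.9 RPKM, Ccnb2 from 31.0 to 18.1 RPKM and E2f2 from 6.79 to 4.51 RPKM, and Rb1 rose from 4.98 to 9.79 RPKM; the loci of Cdc20 and Rb1 overlap another tested gene. In the Polycomb list 6 of 28 fell and 0 rose, also adjusted over the list alone (percentile 40.0), among them Pcgf5 (11.2 to 5.68 RPKM), Rybp (16.2 to 10.4 RPKM), Aebp2 (137 to 94.8 RPKM) and Bmi1 (7.71 to 5.29 RPKM). Cholesterol synthesis had 4 of 21 lower, with Sqle from 34.3 to 20.7 RPKM, and 1 higher, Lss, from 6.09 to 9.06 RPKM (percentile 7.24; 4 passed adjusted over the list alone). Of 13 commonly used reference genes 2 rose and 3 fell, a share not different from other genes (Fisher's exact test, adjusted p = 0.451): Hprt rose from 15.9 to 30.2 RPKM and Gusb from 4.04 to 6.40 RPKM, Actb fell from 689.8 to 275.7 RPKM and Ywhaz from 44.9 to 26.8 RPKM, and 5 passed adjusted over the list alone (percentile 17.6).

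Housekeeping groups had fewer calls than other genes. Ribosomal protein genes were called in 6.94% of 72 (4 lower, among them Rpl6 and Rpl8, and 1 higher, Rpl3), and genes of oxidative phosphorylation in 6.98% of 86, with Ndufs6 falling from 34.7 to 18.5 RPKM and Cox6b2 rising from 121 to 180.0 RPKM. Fisher's exact test gave adjusted p-values of 0.0005 and 0.0001, and list medians stood at percentiles 17.9 and 68.9. The ribosomal protein median was -0.12 against -0.07 in matched lists, and that of oxidative phosphorylation -0.05 against -0.07. Since the shares were not matched on abundance or gene length, fewer calls do not show steadier expression. Adjusted over the list alone, 0 and 4 passed. Of 49 replication-dependent histone genes 1 was called, Hist2h2bb, chosen after its value was seen, and 0 adjusted over the list alone (percentile 9.49); the most abundant, Hist1h1a and Hist1h3e, were at 167 and 155 and at 157 and 130 RPKM.

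Small RNA genes were seldom called. In the small nuclear and nucleolar RNA list 2 of 87 were called and also passed adjusted over the list alone, Rmrp (10139 to 17826 RPKM) and Scarna2 (401385 to 718580 RPKM), both higher. Its median of 0.17 lay above all matched random lists (adjusted permutation p = 0.0016), whose median was -0.15, though 85 members did not pass. Matching was on RPKM and not on gene length. Without overlapping loci the median was 0.26 over the 11 left (adjusted permutation p = 0.0029). Of 159 miRNA loci 3 were called and 1 adjusted over the list alone: the host gene Mir124a-1hg fell from 36.4 to 19.8 RPKM, while Mirlet7a-1 and Mir6546 were listed at 0 without doxycycline. The median of -0.12 stood at percentile 86.4 (adjusted permutation p = 0.501). Without overlapping loci, an alternative chosen after seeing the data, it was 0.20 over the 42 left, above all matched lists (adjusted permutation p = 0.0016).

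Lists with under 3 measured members had no test: 2 Argonaute genes, with Ago2 also passing adjusted over the list alone; 1 Hox gene, Hoxc12, at 0.542 and 3.36 RPKM with a q-value of 0.217 in the authors' deposited table; 1 gene of the 2-cell-like state, Eif1a, which fell from 56.3 to 42.7 RPKM. Of the primitive streak and mesoderm list and the mitochondrially encoded list 0 genes were measured.

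By chromosome, only chromosome 3 differed from matched sets of genes among 20 tested. Its 506 genes had a median log2 fold change of -0.11, at percentile 0.01 (adjusted permutation p = 0.0080), with 52 higher and 85 lower. With an RPKM minimum of 5 the adjusted permutation p was 0.0660, and with a pseudocount of 1 it was 0.0080. A trisomy of chromosome 8, common in ESC, would show here only if its share differed between the groups. That chromosome had a median of -0.01 at percentile 99.5 (adjusted permutation p = 0.110).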

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

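Outside the tested genes, 33 genes stood at 100 RPKM or more with doxycycline and were listed at 0 without it. Only 1 went the other way, and this imbalance led to the closer look. All 33 are miRNA or small nucleolar RNA genes, from 100.3 RPKM up to 3830 RPKM for Mir7229. Of these, 9 share 4 exact RPKM values, and the authors' program left all 33 untested for lack of reads. Their RPKM values therefore do not show a rise. No explanation was tested.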

How the results depend on the processing

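Removal of overlapping loci and the matching on GC content were chosen after seeing the data. The number of called genes went from 2833 to 1853 at a q threshold of 0.01 (865 higher) and to 875 with a log2 fold change of at least 1 (521 higher), by construction. The primed and neuroectoderm median was -0.19 with an RPKM minimum of 5 and -0.38 with a pseudocount of 1, both past no threshold. Without overlapping loci the pluripotency median of -0.31 no longer passed, and that of miRNA loci, 0.20 over 42 genes, came to pass. At a q threshold of 0.01 calls made up 26.9% of miR-290 and miR-302 targets and 26.5% of pluripotency genes, no longer enriched, and 39.3% of stress response genes, now enriched; with an RPKM minimum of 5 the target share of 44% no longer passed. Chromosome 3, at -0.12, did not pass with that minimum. Relative to matched sets, sites of miR-290 and miR-302 turned from 0.015 to -0.063 as 8mers. Sites of miR-15/16 turned from 0.021 to -0.0052 as 8mers (-0.0039 matched on UTR GC) and missed the threshold at 0.021 in the shortest UTR and 0.010 matched on UTR GC. Sites of miR-21, -0.050 as planned, missed it at -0.043 as 8mers, -0.026 in the shortest UTR, -0.034 in coding sequence, -0.026 matched on UTR GC and -0.022 as 8mers matched on UTR GC. With an RPKM minimum of 5, miR-17, miR-20, miR-93 and miR-106 (-0.023) and miR-26 (-0.028) came to pass. The cause was not tested. The other 324 values recomputed for these comparisons kept their direction where called and their side of the threshold. Some could not do otherwise: an RPKM minimum of 1 and no minimum moved nothing, and centring and upper-quartile scaling shift every gene alike, by too little to turn a call. For that reason the 206 values of named genes under both say nothing on stability. The stress response median ranged from 0.30 to 0.60, FGF/ERK feedback from -0.51 to -0.34 and trophoblast from -1.74 to -1.47, upper-quartile scaling included. No paired analysis was possible because the table holds 1 value per group; leaving out each library, a replicate block, edgeR and DESeq2 were not run for the same reason. Depth limits which genes could be tested, and its size is unknown.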

Other observations

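Tests of the stress response against the abundance trend, of cytoplasmic carry-over and of fewer differentiated cells were chosen only after the result was seen; the lists named here for the actin cytoskeleton, YAP and REST were written after the other lists were seen and before their own values.

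Genes of the actin cytoskeleton and targets of serum response factor (SRF) lay below matched lists. Of 27 measured, 12 fell and 2 rose, and 17 passed adjusted over the list alone. Tagln2 fell from 47.8 to 24.3 RPKM, Cfl1 from 96.0 to 58.3 RPKM and Tpm4 from 38.1 to 22.8 RPKM, whereas Zyx and Lima1 rose from 2.60 to 6.18 and from 20.8 to 31.2 RPKM. Of 16 targets of YAP, the effector of the Hippo pathway, 7 fell and 0 rose, a share of calls that did not pass (Fisher's exact test, adjusted p = 0.217), with Nt5e from 10.7 to 2.29 RPKM, Amotl1 from 12.6 to 7.21 RPKM and Amotl2 from 26.9 to 18.0 RPKM. These examples were chosen after their values were seen. The YAP targets Cyr61 (5.43 and 4.50 RPKM) and Axl (3.01 and 2.87 RPKM) did not pass, nor did Ctgf, a well-known target left out of that list, at 5.78 and 7.95 RPKM.

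Of 28 integrated stress response genes 12 rose and 16 did not pass, and the list's median was raised. The general rise of low-abundance genes is argued against as the whole cause, since the list's median lay at percentile 99.99 of lists matched on RPKM. Doxycycline blocks mitochondrial ribosomes, a known inducer of ATF4 targets, and so may act without the transgene. That cannot be told apart from an effect of AGO2, because 0 groups received doxycycline without the transgene. An effect of the induced AGO2 stays open and untested for the same reason.

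Of 14 called endoderm, fibroblast and trophoblast markers 10 fell, keratin and collagen genes among them, though of these 3 lists only the trophoblast median lay outside matched lists. Fewer differentiated cells in the doxycycline cultures cannot be told apart from a change within ESC. The other 4 markers rose and the pluripotency list lay at percentile 0.46, but ESC themselves express many of these genes, and that baseline would hide the loss of a small share of other cells. Another candidate explanation is lower activity of SRF or of YAP, whose lists lay at percentiles 0.34 and 0.90 of matched lists (adjusted permutation p = 0.0210 and 0.0273 over 3 added lists). Both rest on RNA alone, and whether either follows AGO2 or doxycycline was not tested.

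Among tested genes, those of low abundance were more often higher with doxycycline. Genes low in both groups were left untested, which can shape the lowest decile. The median also went from 0.24 in decile 2 to -0.18 in decile 9. All means there are 3.18 RPKM or more, above the 2.312 RPKM that every tested gene reached in its higher group. This argues against a limit at that RPKM as the whole cause. Whether the filter shapes the trend in other ways was not tested. More background reads are argued against: over 1601 genes of receptor and keratin-associated families silent in ESC, mean RPKM was 0.755 times that without doxycycline (95% bootstrap interval 0.572 to 1.02), although 111 of them were listed above 0 with doxycycline and 91 without. GC content is argued against too, since the gap between the lowest and highest deciles of abundance, 0.61 on the log2 scale over genes with a known transcript GC, was 0.60 on average within deciles of transcript GC. Less carry-over of cytoplasmic mRNA may also lower abundant genes; the ribosomal protein list, at percentile 17.9 of matched lists, cannot be told apart from either outcome. The authors' normalization and the depth of the libraries stay open, as no value per library is at hand.

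If the induced AGO2 silenced mRNAs with miR-290 and miR-302 sites, genes with a site may be expected to lie below matched genes. They lay at percentile 93.2 for the 7mer-m8 site, within the spread of random sets and on the other side, and at percentile 0.21 for the 8mer, so the tests do not decide. Only RNA of the chromatin pellet was sequenced, so silencing of mRNA in the cytoplasm is not covered. Matched also on 3′ UTR GC, an alternative chosen after seeing the data, the 8mer lay at percentile 0.55 (adjusted permutation p = 0.125). Its shift was -0.059 against -0.063 before. That matching also used 5 bins of UTR length instead of 10, so the small difference cannot be credited to GC content alone. The 7mer-m8 sequence in coding regions lay at percentile 0.50 (adjusted permutation p = 0.0561), and over all alternatives the adjusted p ranged from 0.0484 to 0.829.

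Kcnt2, a channel gene known from neurons, is among the largest rises, which release of genes repressed by REST might explain. A list of 15 such genes lay at percentile 15.0 of matched lists (adjusted permutation p = 0.3002), with 3 higher (Dnm1, Kcnh3 and Grin1) and 3 lower (Tmem198, Stmn2 and Rims2), so no shared rise was seen.

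Some of the largest falls are of adjacent genes, such as Atp1a4 with Casq1 and Col4a1 with Col4a2. Fold changes of adjacent, non-overlapping genes within 50 kb (5518 pairs) had a Spearman's rho of 0.108 across genes, above the central 95% of 1000 shuffles within RPKM bins (-0.02 to 0.03), and adjacent genes farther apart had 0.062. Of 405 near pairs with both genes called, 282 moved the same way. Neighbouring genes may thus share part of their change, which reads running past gene ends could also give; this was not tested.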
